A study of Mus musculus with 2 samples.

How the data were processed

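Libraries were made with 10x Genomics 3' chemistry from sorted cells of NALT and MedLN, 1 library per group, and sequenced on an Illumina NovaSeq, per the labels' protocols. The authors deposited a filtered count matrix per library, whose values are UMI counts per gene and cell. The counts were made with Cell Ranger 6.0.1 per the file headers, whereas Cell Ranger 5.0.1 is named per the submitters' processing notes; both are given because nothing in the sources used here decides between them. The build mm10 and Seurat, without a role, are also named per the submitters' processing notes. Of 32285 gene IDs 32158 (99.6%) were found in GENCODE vM21, from which positions were taken. The 392 immunoglobulin genes were picked by symbol from the deposited gene list. There are 78 genes that share their symbol with another gene, so genes were joined by ID.

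Cells with at least 500 genes, at least 1000 UMIs and under 10% mitochondrial UMIs were kept. This removed 1196 NALT barcodes (17.1%) and 1192 MedLN barcodes (15.2%). Scrublet, as built into scanpy 1.11.5, was run per library with a fixed seed; it called 111 (1.91%) and 173 (2.60%) doublets, which were removed. The kept cells held 37563899 and 59618839 UMIs, of which 0.753% and 1.33% came from immunoglobulin genes. Median mitochondrial shares were 5.19% and 5.41%. Both libraries were clustered together without integration: counts scaled to 10000 per cell and logged, 2000 variable genes without immunoglobulin, mitochondrial and ribosomal protein genes, 30 principal components, 15 neighbours, and Leiden clustering at resolution 1.0 with seed 1. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.

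The cell filter, clustering settings, scaling, gene lists, cell type markers, the size rule and the rule for named genes library-wide and in germinal center-like cells were set before the data were examined. The grouping of clusters was chosen after the clusters were seen: Cd3e-high and Cd79a-high clusters are those where at least 50% of cells held a UMI of the gene, except that a median natural killer marker log2 fold above 1 kept a cluster out of the Cd3e-high set (cluster 9, at 3.72). Part of the grouping within the Cd79a-high clusters rests on an item not reported here. Cluster 14 was called plasmablast-like from a median marker log2 fold of at least 2. Clusters 6 and 8 are led by mitotic and histone genes and were not named; cluster 0 was called germinal center-like from fixed markers. Clusters 4, 5 and 10 form the other Cd79a-high set. Cd3e-high clusters were not given a type name, because early activation genes lead cluster 3, histone genes cluster 13 and interferon genes cluster 15. No cluster met the markers of resting B cells, which had been planned as background for Igha, so Cd3e-high cells took that place. Plasmablast-like cells were under 100 in NALT, so gene-level comparison was left out there.

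UMIs were summed per library and cell set and divided by the total outside immunoglobulin genes and scaled to give CPM. Folds carry exact conditional binomial 95% intervals, shares exact binomial ones and differences of shares Newcombe ones, all for counting error only. Against 0 counts a floor of 3 counts was used. Named genes were those with the largest log2 ratio of CPM plus 5, among genes with at least 100 UMIs: 12 per direction library-wide and 8 in germinal center-like cells. Immunoglobulin V, D and J segments, ribosomal protein, mitochondrial, Xist and Y-linked genes and predicted genes were left out. The same rule gave 12 per direction in the other Cd79a-high set and 8 in Cd3e-high cells, numbers chosen after the data were seen. A barcode holding at least 20% of a gene's UMIs in a library was looked at on its own. The 25 gene lists held 471 genes, of which 468 were found. A list was described by the median log2 fold of members with at least 50 UMIs and its percentile among 10000 random lists matched on expression in 20 bins. A cell was given the heavy chain constant gene with most UMIs, from at least 3 such UMIs, and a light chain type by the same minimum. Shares of cells with a UMI were taken after thinning to 2000 UMIs, which leaves out 190 NALT and 254 MedLN cells over all sets.

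The fold and list steps were tested on simulated counts with 200 changed genes, drawn per gene as independent Poisson counts on library sums. Clumping of UMIs in single cells and co-expression of list genes were not simulated. Coverage near 95% was therefore built in, and the values below check the code, not the error of the real counts. Over 11242 genes library-wide the interval covered the true fold for 95.6%, 95.7% of 2-fold and 98.1% of 4-fold changes passed the size rule, and 0.263% of unchanged genes did. In germinal center-like cells (6227 genes) these were 95.1%, 88.1%, 89.0% and 0.760%. For the other Cd79a-high set (8968 genes) they were 95.5%, 97.0%, 96.0% and 0.330%, and for Cd3e-high cells (9650 genes) 95.4%, 98.9%, 93.6% and 0.275%. A shifted list reached percentile 100 in each, and of the lists left unshifted 0 of 24, 0 of 20, 1 of 22 and 2 of 21 lay outside the central 95% of random lists.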

Results

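Single-cell RNA sequencing profiled transferred B cells from 2 lymphoid sites of mice: NALT, usually read as nasal-associated lymphoid tissue but given in the sample labels as nasal-associated lymph nodes, and the mediastinal lymph nodes (MedLN), which drain the lung. Wild-type hosts had received green fluorescent B1-8hi B cells, whose knocked-in heavy chain binds the hapten NP together with a lambda light chain, and red fluorescent OT-II CD4 T cells, which recognise ovalbumin. They were then immunised through the nose with NP-ovalbumin and the adjuvant MPLA. Tissue was taken on day 5, GFP-positive cells were sorted, and 12000 cells per library were loaded with 8000 targeted. The title of the series concerns the origin of IgA-secreting cells of the nasal turbinates, and the design sets the site near the nose against the site near the lung. There was 1 library per group, so no difference below has a replicate check, no test was run, and every interval covers counting error only. The deposited counts held 7013 barcodes and 40822537 UMIs for NALT (median 4828 UMIs and 1733 genes) and 7841 barcodes and 64400188 UMIs for MedLN (median 6392 UMIs and 2026 genes). After filtering, 5706 NALT cells with a median of 5369.5 UMIs and 6476 MedLN cells with a median of 7121.5 UMIs remained. Gene positions are on mm10 (GRCm38), from the GENCODE vM21 annotation; the annotation release used by the authors is not given in the sources used here.

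B-lineage cells were a minority of both libraries, although the labels name the cells as sorted GFP-positive B cells. Clusters in which most cells held a UMI of Cd3e, a chain of the T cell receptor complex, without the natural killer-marked cluster 9, made up 56.7% of NALT cells (95% exact binomial interval 55.4 to 58.0) and 51.5% of MedLN cells (50.2 to 52.7). In these Cd3e-high clusters 97.6% of NALT and 97.3% of MedLN cells held a UMI of Trac, the T cell receptor alpha constant gene, against 5.14% and 4.63% in the Cd79a-high clusters 4, 5 and 10, at median depths of 4550 and 5764 UMIs against 6762 and 8771. Cd4 was seen in 69.2% and 73.4% of Cd3e-high cells and Cd8a in 0.0309% and 0.180%. Clusters high in Cd79a, which encodes a signalling chain of the B cell receptor, held 2413 NALT cells (42.3%) and 2917 MedLN cells (45.0%). Clusters 9 and 11, led by natural killer and myeloid genes and left unnamed, held 0.981% and 3.51%; in cluster 9 Cd3e was detected in 81.7% of its 25 NALT and 57 MedLN cells.

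**Figure D1:**
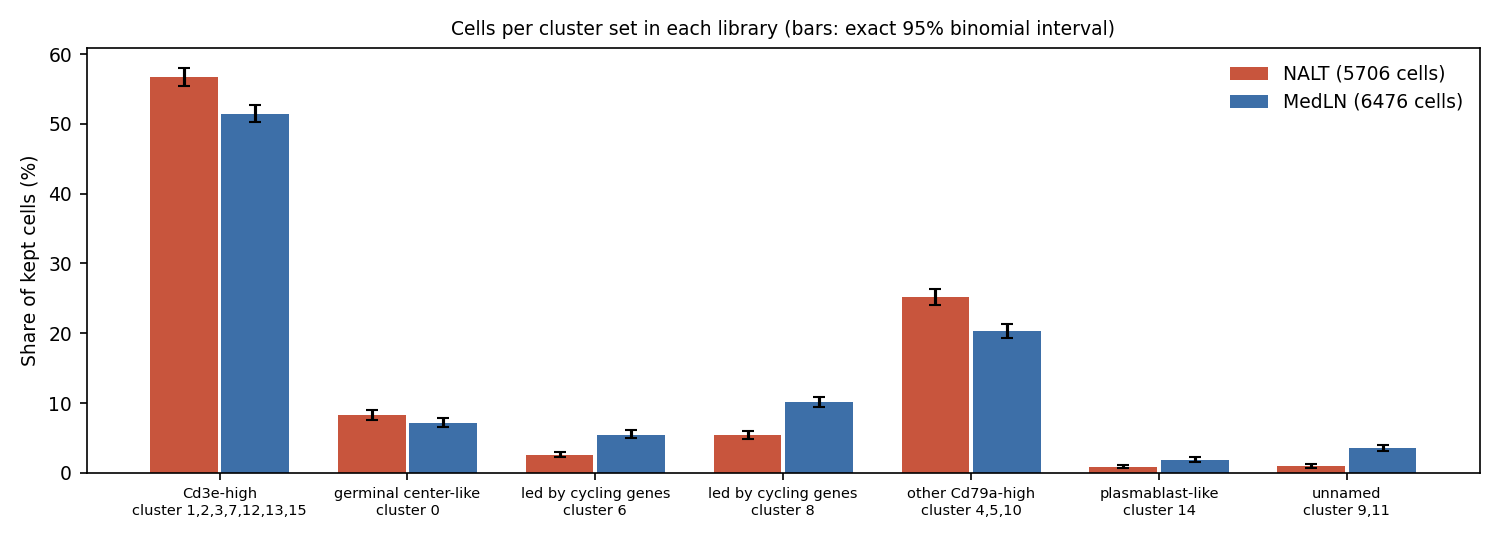
Share of kept cells (%, vertical axis) in each cluster or set of clusters for NALT (red) and MedLN (blue), with exact 95% binomial intervals as error bars. Cd3e-high clusters hold 56.7% and 51.5% of cells, and cluster 8, led by histone genes, 5.35% and 10.1%.

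Among Cd79a-high cells, NALT held fewer plasmablast-like cells than MedLN and more cells of clusters 4, 5 and 10. Cluster 0, named germinal center-like from fixed markers such as Rgs13 and Lipc, made up 19.6% of Cd79a-high NALT cells (18.0 to 21.2) and 16.0% of MedLN cells (14.7 to 17.4). Clusters 6 and 8 also matched the germinal center markers best of all fixed marker sets, with S1pr2 in 59.2% and 75.8% and Bcl6 in 52.1% and 54.7% of their cells, unthinned, at median depths of 13653 and 14738 UMIs. These shares were 5.1% and 4.6% in cluster 10 at 16449 UMIs, and 60.8% and 43.4% in cluster 0 at 8095 UMIs, so cluster 0 is not ordered against clusters 6 and 8. They were set apart because mitotic genes lead cluster 6 and histone genes cluster 8, and both were larger in MedLN: of all kept cells, cluster 6 made up 2.59% in NALT and 5.48% in MedLN, and cluster 8 5.35% and 10.1%. The order seen in cluster 0 therefore does not extend to these clusters. NALT minus MedLN was 3.59 percentage points for cluster 0. Cells passing a stricter filter were clustered again and the germinal center-like set was named anew, where the difference was -5.22. That set need not match cluster 0, so the turn cannot be laid to the filter alone. Plasmablast-like cluster 14, marked by Jchain, Prdm1 and Xbp1, held 49 NALT cells (2.03%, 1.51 to 2.68) and 122 MedLN cells (4.18%, 3.49 to 4.97). The other Cd79a-high clusters 4, 5 and 10 made up 59.6% (57.6 to 61.6) and 45.1% (43.3 to 47.0). Within this set Ccr6, a chemokine receptor found on memory B cells, was detected in 90.5% of NALT and 90.6% of MedLN cells. Cd38, also a fixed memory-like marker, was less alike, at 46.8% of NALT and 81.2% of MedLN cells, unthinned. Ccr6 was detected in 10.9% and 12.2% of Cd3e-high cells, at median depths of 4550 and 5764 UMIs against 6762 and 8771. The set was split by library: cluster 4 held 1239 NALT and 16 MedLN cells, and cluster 5 held 144 and 1140, and a cluster mostly of 1 library cannot be told from that library. The plasmablast-like difference moved from -2.15 to -7.50 percentage points when cells passing the stricter filter were clustered again. All of these shares were taken after the GFP sort and from deeper cells in MedLN, with a median of 10864 UMIs in Cd79a-high cells against 7349 in NALT.

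Igha, the constant gene of the IgA heavy chain, was the leading heavy chain gene far more often in NALT than in MedLN B cells outside the plasmablast-like cluster. In the other Cd79a-high clusters 930 of 1344 called NALT cells were led by Igha (69.2%, 66.7 to 71.7), against 130 of 1231 MedLN cells (10.6%, 8.90 to 12.4). In germinal center-like cells the shares were 43.2% (38.3 to 48.2, 172 of 398) and 24.4% (20.3 to 28.9, 99 of 406); this difference of 18.8 percentage points was 44.5 under the stricter filter. Plasmablast-like cells went the other way, with 3 of 47 NALT cells (6.38%, 1.34 to 17.5) and 51 of 121 MedLN cells (42.1%, 33.2 to 51.5) led by Igha. The difference had the same sign in each Cd79a-high cluster with over 50 cells in both libraries: 59.7% and 14.9% in cluster 6, 52.6% and 15.4% in cluster 8, 18.7% and 10.9% in cluster 5, and 78.0% and 7.19% in cluster 10. In cluster 4, almost all of it from NALT, 74.1% of called NALT cells were Igha-led. Igha (ENSMUSG00000095079) lies on chromosome 12 from 113254830 to 113260236 on the minus strand.

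Ighm, the constant gene of IgM, led 53.4% of called MedLN cells and 14.1% of NALT cells in the other Cd79a-high clusters, and 42.9% and 13.1% in germinal center-like cells. By the same rule 470 of all 3237 NALT and 772 of all 3332 MedLN Cd3e-high cells were Ighm-led. In NALT this compares with 189 of all 1439 other Cd79a-high and 52 of all 472 germinal center-like cells. The NALT Ighm-led shares of these B cells were therefore not above that of Cd3e-high cells. Ighg2b led 15.3% of NALT and 25.3% of MedLN cells in the other Cd79a-high clusters, and 39.7% and 24.4% in germinal center-like cells. In the plasmablast-like cluster Ighg2b led 68.1% of NALT cells (52.9 to 80.9) and 20.7% of MedLN cells (13.8 to 29.0). Ighg1 led 2.01% of NALT and 5.17% of MedLN germinal center-like cells. Ighe led 0 of 398 called NALT cells there, with an interval reaching 0.923%. The 3' reads cannot tell germline transcripts from those of switched cells.

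**Figure D2:**
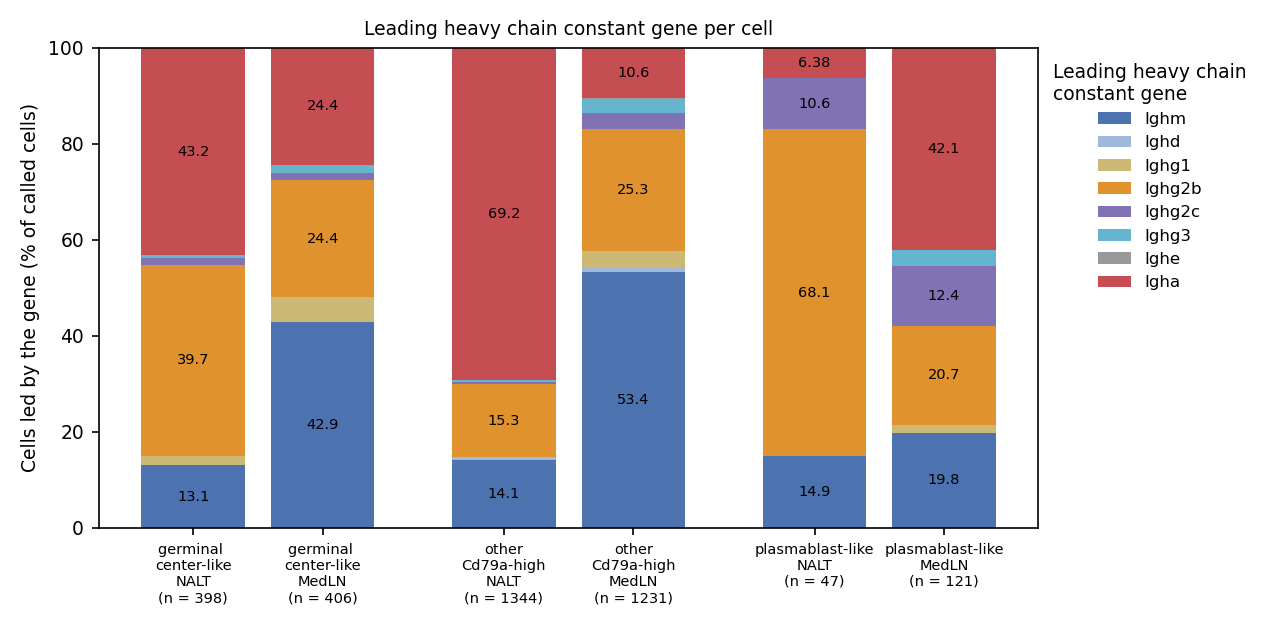
Share of called cells (%, vertical axis) led by each heavy chain constant gene, per cell set and library, with the number of called cells under each bar. Igha takes 43.2% of germinal center-like cells in NALT and 24.4% in MedLN, 69.2% of other Cd79a-high cells in NALT and 10.6% in MedLN, and 6.38% and 42.1% of plasmablast-like cells.

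With each cell thinned to 2000 UMIs, an Igha UMI was found in 76.2% of NALT and 18.1% of MedLN other Cd79a-high cells, leaving out 29 and 13 shallower cells. The unthinned shares were 84.3% and 32.4%. Thinned germinal center-like shares for Igha were 46.9% and 28.9%, with 5 cells left out in each library, against 62.1% and 45.1% unthinned. In Cd3e-high cells, used as background for Igha, the thinned Igha shares were 3.82% and 5.93%, with 125 and 112 cells left out. The unthinned Igha shares there were 8.28% and 17.6%. Median depths were 6797 and 9455 UMIs in germinal center-like cells and 4550 and 5764 in Cd3e-high cells. Summed over whole libraries, Igha was 1.72-fold lower in NALT (1.69 to 1.74), and the 122 plasmablast-like cells of MedLN held 52819 of that library's 62693 Igha UMIs.

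Light chain use was close to uniform. Lambda constant genes led 94.5% of NALT and 94.6% of MedLN germinal center-like cells, 96.3% and 98.7% of other Cd79a-high cells, and 49 of 49 and 121 of 122 plasmablast-like cells. Ighv1-72, the V gene of the B1-8 heavy chain, gave 81.0% of the Ighv UMIs of NALT germinal center-like cells (70.9 to 88.7, of 84) and 80.2% in MedLN (71.7 to 87.0, of 116).

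In the other Cd79a-high clusters, NALT cells carried more RNA of the transcription factor gene Tfcp2l1 and of Apoe, and less of Slpi and Cd22. Tfcp2l1 had 621 UMIs in NALT and 3 in MedLN, a ratio of 252 (86.0 to 1230). Apoe, a lipid carrier, was 7.20-fold higher (7.01 to 7.41), AA467197 21.8-fold (16.6 to 29.3), Osgin1 32.1-fold (20.3 to 53.8), and Cd244a, a receptor of the SLAM family, 19.1-fold (13.8 to 27.1). Igha UMIs were 5.89-fold higher (5.66 to 6.14). Cd7 had 257 UMIs in NALT and 0 in MedLN, at least 104-fold higher from a floor of 3 counts. Ccl22, which attracts CCR4-bearing T cells, was 31.4-fold higher (18.5 to 58.1); without the cycling cluster 10 its log2 fold moved from 2.67 to 1.54. Col27a1, Grasp, Car2 and Neurl3 were 60.2, 12.6, 12.2 and 11.6-fold higher. Tfcp2l1, Apoe, AA467197, Osgin1, Cd244a and Ccr1 are also leading genes of cluster 4, and Zeb2, Ffar2 and Pcp4 of cluster 5. The comparison is mostly of cluster 4 in NALT with cluster 5 in MedLN.

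Lower in the same NALT cells was Slpi, a secreted protease inhibitor (310-fold, 121 to 1140, from 4 and 1510 UMIs). Ffar2, a receptor for short-chain fatty acids, was 24.8-fold lower (17.7 to 35.8) and Pcp4 25.3-fold lower (16.6 to 40.7). Cd22, an inhibitory coreceptor of B cells, was 5.18-fold lower (4.64 to 5.79), and Zeb2 4.95-fold (4.43 to 5.53). Lipc, Cacna1e, Ankrd37, Il9r, Pglyrp1 and Ighg1 were 8.82, 7.53, 7.17, 6.84, 6.75 and 5.39-fold lower. Tfcp2l1 (ENSMUSG00000026380) lies on chromosome 1 from 118627945 to 118685168, and Slpi (ENSMUSG00000017002) on chromosome 2 from 164354070 to 164389095.

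**Figure D3:**
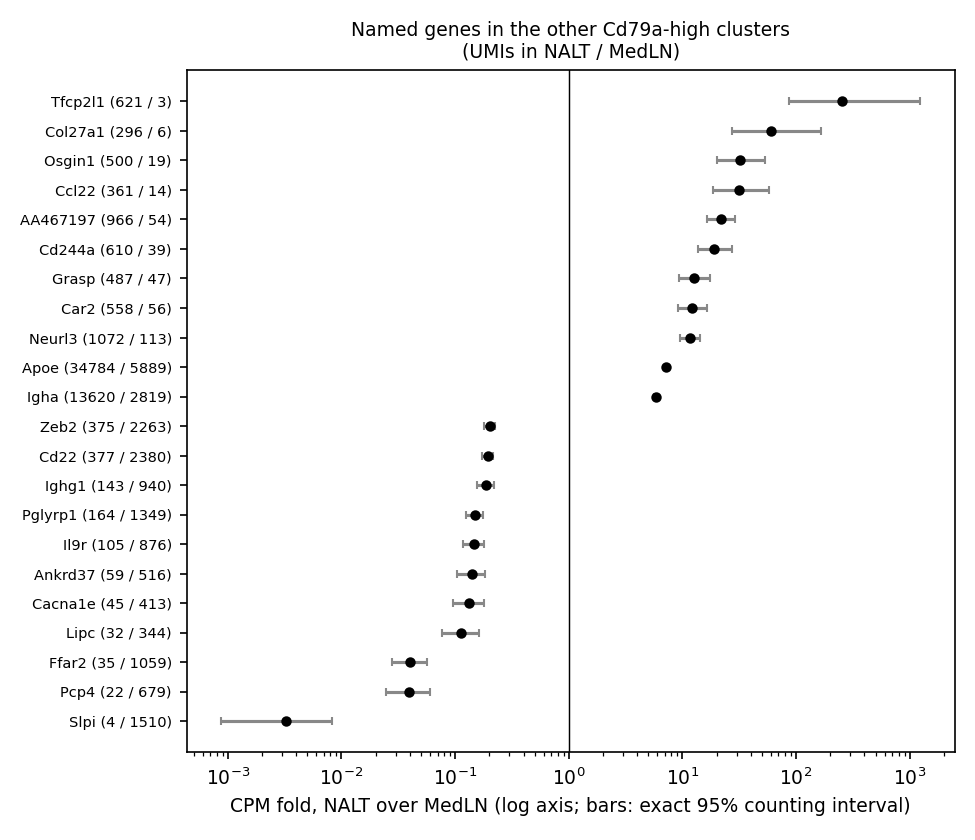
Fold of CPM, NALT over MedLN, on a log axis for genes named in the other Cd79a-high clusters, with exact 95% counting intervals as bars and UMIs in NALT and MedLN beside each name. Cd7, with 0 MedLN UMIs, is left out; Tfcp2l1 stands at 252 and Cd22 at 0.193.

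TGF-beta response genes stood higher in NALT in these cells, with a median of 0.81 on the log2 scale. Of the 15 measured members 10 were at least 1.5-fold higher with an interval excluding 1, 1 was lower and 4 neither. Runx2, a transcription factor of this pathway, was 10.9-fold higher (8.30 to 14.5) and Skil, a feedback inhibitor, 2.88-fold (2.65 to 3.14), while Id3 was at 0.589 (0.509 to 0.680). Dissociation and stress genes moved with them (median 0.51; 11 higher, 1 lower, 12 neither), with Nr4a1 at 7.19-fold and Klf6 at 3.69-fold. The homing list had 7 members higher and 6 lower of 21, with Cxcr4 6.48-fold higher (5.34 to 7.92), Ccr1 3.52-fold higher and Itgb1, the beta-1 integrin chain, 3.97-fold lower (3.58 to 4.42). T cell genes also stood higher in these B cells (median 0.40; 6 higher, 0 lower, 6 neither), with Trbc1 at 2.40-fold; the median was 0.13 with called doublets kept. Cst3, a myeloid-list gene, was 3.16-fold higher (3.05 to 3.28) and the myeloid median was 0.09, 1.23 with members of at least 500 UMIs and -0.24 without the cycling cluster 10. The erythroid median was 1.01, with Hbb-bs at 39.2-fold (17.7 to 108) from 193 and 6 UMIs. Without the barcode holding most of its UMIs in each library, Hbb-bs was also higher in NALT germinal center-like and Cd3e-high cells. Its rise was therefore not particular to this set. Runx2 (ENSMUSG00000039153) lies on chromosome 17 from 44495987 to 44814797 on the minus strand.

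Cell cycle genes stood lower in the NALT cells of this set, and most of the difference went with cycling cluster 10, which was 3.89% of the set in NALT and 12.2% in MedLN. Of the 26 G2/M genes 24 were at least 1.5-fold lower (median -1.05), among them Nusap1 (3.01-fold, 2.60 to 3.49) and Birc5 (2.75-fold). Of the 24 S phase genes 17 were lower (median -0.60), with Rrm2 2.25-fold and Mcm3 2.17-fold lower. The dark zone list, which shares many of these genes, had 9 members lower and 2 higher (median -0.98). Without cluster 10 the G2/M median was -0.13 with 3 of 21 members lower, the S phase median -0.21 with 6 of 21 lower, and the dark zone median -0.02 with 1 of 11 lower. Glycolysis and hypoxia genes had 7 lower, 1 higher and 12 neither (median -0.43), with P4ha1 3.05-fold lower. Interferon genes had 7 lower and 3 higher of 31 (median -0.25); Gbp2 was 2.29-fold lower and Cd274 3.58-fold higher. MYC response (-0.25; 1 higher, 3 lower, 21 neither), secretory pathway (-0.18; 1, 6, 28) and oxidative phosphorylation (-0.20; 0, 0, 39) medians lay at or below percentile 0.36 of 10000 matched random lists, and were -0.11, -0.09 and -0.15 without cluster 10, where MYC response (percentile 3.24) no longer lay outside the central 95%. Each of the 4 light chain constant genes were lower (median -0.64), and 5 of the 8 heavy chain constant genes (median -1.41). Light zone genes were mixed (median 0.07; 4 higher, 3 lower), with Egr1 3.68-fold higher and Myc 2.28-fold lower.

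Germinal center-like cells of cluster 0, with 472 NALT and 466 MedLN cells, were grouped across both libraries by their likeness, so their differences cannot be weighed against those of the library-split clusters. Cd83, an activation marker of light zone cells, was 2.29-fold higher in NALT (1.99 to 2.63). Tiparp was 3.75-fold higher (2.72 to 5.23), Plac8 3.56-fold (2.63 to 4.87), Sema4b 3.49-fold (2.61 to 4.72), Pik3ip1 3.27-fold (2.22 to 4.91) and Pdcd4 2.44-fold (2.05 to 2.91). Igha UMIs were 1.82-fold (1.70 to 1.95) and Ighg2b UMIs 2.03-fold (1.90 to 2.18) higher. Ighg3 (3.70-fold), Ighm (2.79-fold), Ighg1 (2.84-fold), Ankrd37 (3.32-fold), Slpi (3.70-fold), Hbb-bh1 (2.51-fold), Fosb (2.88-fold) and Rgcc (2.36-fold) were lower. Globin genes also met the rule for named genes, but 1 NALT barcode held 85.0% of the 341 Hbb-bs UMIs, 82.3% of 130 for Hba-a1 and 77.6% of 107 for Hba-a2. Without it and the top MedLN barcode Hbb-bs was 23.0-fold higher (7.43 to 115). Cells were clustered again under the stricter filter, so its germinal center-like set need not match cluster 0. There 9 of the 16 named genes remained at least 1.5-fold apart in the reported direction. Fosb moved from a log2 fold of -1.19 to -0.20, Tiparp from 1.54 to 0.58, Ankrd37 from -1.30 to -0.67 and Rgcc from -1.13 to -0.47. Slpi moved the other way, from -1.30 to -3.17, and Ighm from -1.47 to -2.57.

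In the same cells TGF-beta response genes had a median of 0.36 (4 higher, 0 lower, 8 neither), with Id2 at 2.5-fold (1.82 to 3.47) and Smad7, an inhibitory SMAD, at 1.92-fold (1.69 to 2.18). Homing genes had a median of 0.26 (5 higher, 1 lower, 10 neither): Ccr6 was 2.11-fold higher (1.46 to 3.07), and Cxcr3, a receptor for interferon-induced chemokines, 2.59-fold lower (1.71 to 4.03). MHC class II genes had a median of 0.27 with none of 14 past 1.5-fold, and light zone genes 0.15 (3 higher, 2 lower, 15 neither). Apoptosis and survival genes had a median of 0.15 (0 higher, 1 lower, 17 neither), with Tnfrsf13c, the BAFF receptor, at 1.46-fold. S phase (-0.19), oxidative phosphorylation (-0.18) and glycolysis (-0.28) medians were lower, with at most 1 member past 1.5-fold in each. The heavy chain constant list had a median of -0.86, which turned to 0.85 when only members with at least 500 UMIs were kept. Stress genes (-0.05) and T cell genes (0.21) lay at percentiles 14.2 and 86.1 of the random lists, and the T cell median was 0.77 with called doublets kept. The erythroid median was 2.96 and the sex-linked one 0.45. Dark zone (-0.03), G2/M (-0.07), MYC (0.00), secretory pathway (0.07), interferon (-0.10), light chain (0.07) and class switch machinery (0.01) medians lay within the central 95% of theirs; Gcsam was at 0.520 (0.442 to 0.609).

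The proliferation genes Mki67 and Top2a were lower in NALT in the other Cd79a-high set, by 2.0-fold (1.87 to 2.15) and 2.01-fold (1.89 to 2.14) in CPM, the counts scaled to an equal total outside immunoglobulin genes for the set in each library. Without cycling cluster 10 the NALT level of Mki67 was 0.925 (0.801 to 1.07) and that of Top2a 1.09 (0.951 to 1.24) of the MedLN level. In germinal center-like cells they were at 0.974 (0.902 to 1.05) and 0.869 (0.797 to 0.948), so no order was read from the Mki67 share there. Clusters 6 and 8, with a Mki67 UMI in 97.4% and 98.4% of cells, had been set apart from that set, so its shares leave out most cycling cells with germinal center markers. Thinned to 2000 UMIs, Mki67 was seen in 39.2% of NALT and 38.2% of MedLN germinal center-like cells, and Top2a in 26.1% and 29.1%. In the other Cd79a-high set the thinned shares were 8.09% and 14.6% for Mki67 and 10.3% and 15.2% for Top2a, and without cluster 10 they were 5.61% and 6.39% for Mki67 and 7.68% and 7.87% for Top2a. Unthinned, the germinal center-like shares were 62.9% and 75.3% for Mki67 and 45.3% and 63.9% for Top2a. The unthinned other Cd79a-high shares were 19.2% and 31.1% for Mki67 and 25.8% and 31.6% for Top2a. The cells left out were those given above for Igha. Cd3e-high cluster 7, led by S1pr1, Il7r and Klf2 and used as background, had thinned shares of 3.45% and 6.5% for Mki67 and 6.52% and 6.86% for Top2a, with 38 and 23 cells left out, at median depths of 3852.5 and 5147 UMIs. Its unthinned shares were 7.68% and 14.8% for Mki67 and 12.7% and 18.0% for Top2a. Plasmablast-like cells had a Mki67 UMI in 12.5% of 48 NALT cells and 42.6% of 122 MedLN cells (28.6% and 77.9% unthinned). Summed S and G2/M CPM were 2.15-fold and 2.14-fold lower in NALT plasmablast-like cells and 1.13-fold and 1.11-fold lower in germinal center-like cells.

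In Cd3e-high cells, Krt83, Gadd45b, Fosb and Pim1 were the named genes furthest up in NALT by log2 ratio. Fosb was 6.30-fold higher (5.30 to 7.54), Dusp1 4.51-fold (4.08 to 5.00), Tnfaip3, which restrains NF-kB, 4.46-fold (4.13 to 4.83), Gadd45b 4.56-fold (4.23 to 4.92) and Pim1 4.41-fold (4.12 to 4.73). Krt83 was 5.17-fold (4.61 to 5.82), Cebpa 7.05-fold (5.57 to 9.03) and Dusp5 4.44-fold (3.80 to 5.20) higher. The chemokine gene Ccl5 was 42.6-fold lower (22.3 to 93.8, from 9 and 470 UMIs), Iglc1 2.35-fold (2.21 to 2.5), Ddit4 2.20-fold (2.05 to 2.36) and Id3 2.13-fold (2.01 to 2.25). Stress genes had a median of 0.58 (12 higher, 3 lower, 8 neither), with Btg2 1.91-fold lower. S phase (0.36; 1 higher, 0 lower, 23 neither), MYC response (0.26; 2, 0, 23) and secretory pathway (0.19; 3, 0, 31) medians were higher with few members past the size rule, among them Odc1, the first enzyme of polyamine synthesis (3.06-fold), and Dnajb9 (2.88-fold). G2/M and dark zone medians, both 0.20, were also higher. Clusters 13 (144 NALT and 86 MedLN cells) and 12 (175 and 229), with Mki67 in 99.1% and 71.8% of cells, were not left out here. After thinning, Mki67 was seen in 8.90% of NALT and 10.0% of MedLN Cd3e-high cells. Light chain constant (-0.72; 0 higher, 3 lower, 1 neither), heavy chain constant (-0.29; 0, 2, 5) and MHC class II genes (-0.16; 0, 0, 14) lay below the central 95% of random lists. Unthinned, Cd79a was detected in 10.2% of NALT and 14.0% of MedLN Cd3e-high cells, and Ms4a1 in 5.04% and 9.15%. Interferon genes had a median of -0.15 (0 higher, 7 lower, 27 neither), with Ifit1 2.66-fold and Iigp1 2.47-fold lower. Without interferon-led cluster 15, with 8 NALT and 44 MedLN cells, the median was -0.11 (0 higher, 5 lower, 27 neither), and Ifit1 was 1.65-fold (1.20 to 2.28) and Iigp1 2.20-fold (1.78 to 2.73) lower. TGF-beta response genes had a median of 0.13 (percentile 84.6), with Tgif1 at 3.08-fold. T cell (0.02) and glycolysis genes (0.04) lay within the central 95% of the random lists, and oxidative phosphorylation (0.06, percentile 97.7) just above it, with none of its 39 members past the size rule.

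Haemoglobin genes in Cd3e-high cells turned on 1 barcode. Hbb-bs had 469 UMIs in NALT and 3559 in MedLN, of which 3543 lay in 1 MedLN cell, and the same pattern held for Hba-a1, Hba-a2 and Hbb-bt. Without the top barcode of each library Hbb-bs was 31.5-fold higher in NALT (19.1 to 55.6), Hba-a1 27.5-fold, Hba-a2 35.2-fold and Hbb-bt 4.63-fold.

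Over whole libraries, where Cd3e-high cells are the larger part, Tfcp2l1 (646 and 5 UMIs, ratio 204, 86.9 to 630), Osgin1 (15.9-fold, 12.2 to 21.2), AA467197 (13.8-fold, 11.5 to 16.9), Cd244a (10.5-fold, 8.52 to 13.2), Il1r2 (8.68-fold), Krt83 (7.50-fold), Apoe (5.21-fold) and Ccr1 (4.46-fold) were higher in NALT. Tnfaip3 (4.37-fold), Junb (3.72-fold) and Rgs1 (3.28-fold) were also higher. Reg3g, an antibacterial lectin of epithelium, had 1392 NALT UMIs and 0 in MedLN, at least 732-fold higher, but 1357 of them lay in 1 barcode and 35 outside it. With only Cd79a-high clusters the log2 folds of Reg3g and Tnfaip3 moved from 3.08 to 0.20 and from 1.90 to 0.81. Slpi (46.3-fold, 38.8 to 55.9), Ffar2 (18.8-fold), Pcp4 (18.9-fold), Ighg1 (7.83-fold), Fkbp11 (4.28-fold), Ccl5 (4.22-fold), Hbb-bh1 (4.07-fold), Ighg3 (3.68-fold), Lipc (3.46-fold), Ighg2c (3.45-fold) and Ighm (2.74-fold) were lower. Lyz2, a lysozyme of myeloid cells, was 4.36-fold lower (3.82 to 5.00), with 93.3% of its NALT UMIs in 1 barcode and 57.1-fold lower (35.5 to 98.2) without the top barcode of each library; under the stricter filter its log2 fold turned from -1.56 to 0.04. Ccl5 moved from -1.79 to -0.99 under that filter and to -3.10 as a mean of per-cell values. The median log2 fold of all genes was 0.02, and no scaling moved it by more than 0.1.

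Across whole libraries 6 of 25 fixed lists lay above and 13 below the central 95% of matched random lists. Stress genes (median 0.56; 14 higher, 3 lower, 9 neither), TGF-beta response (0.41; 8, 1, 8), T cell (0.36; 1, 0, 15), sex-linked (0.31; 0, 0, 4), homing (0.19; 9, 4, 12) and light zone genes (0.19; 7, 0, 17) were higher. G2/M (-0.55; 0, 15, 11), dark zone (-0.54; 1, 7, 6), S phase (-0.42; 0, 5, 19), secretory pathway (-0.21; 1, 8, 26), heavy chain constant (-1.24; 0, 7, 1) and light chain constant genes (-0.68; 0, 3, 1) were lower. So were MYC response (-0.21; 0, 1, 24), oxidative phosphorylation (-0.17; 0, 0, 39), class switch machinery (-0.17; 0, 0, 12), glycolysis (-0.12; 2, 4, 16), interferon (-0.06; 3, 2, 31), erythroid (-0.45; 0, 1, 3) and myeloid genes (-0.15; 2, 2, 5), with few or no members past the size rule in most. The erythroid median rested on 1 MedLN barcode: without the top barcode of each library Hbb-bs was 35.3-fold (26.4 to 48.1), Hba-a1 40.4-fold and Hba-a2 38.5-fold higher in NALT, while Hbb-bt, less concentrated, was 2.35-fold lower with all cells. The myeloid median turned to 0.40 with members of at least 500 UMIs, where Cst3 (2.03-fold higher) weighs more. MHC class II (0.03), apoptosis (0.01), mitochondrially encoded (-0.08), dendritic (0.18), natural killer (0.05) and stromal or epithelial genes (0.18) lay within that range.

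**Figure D4:**
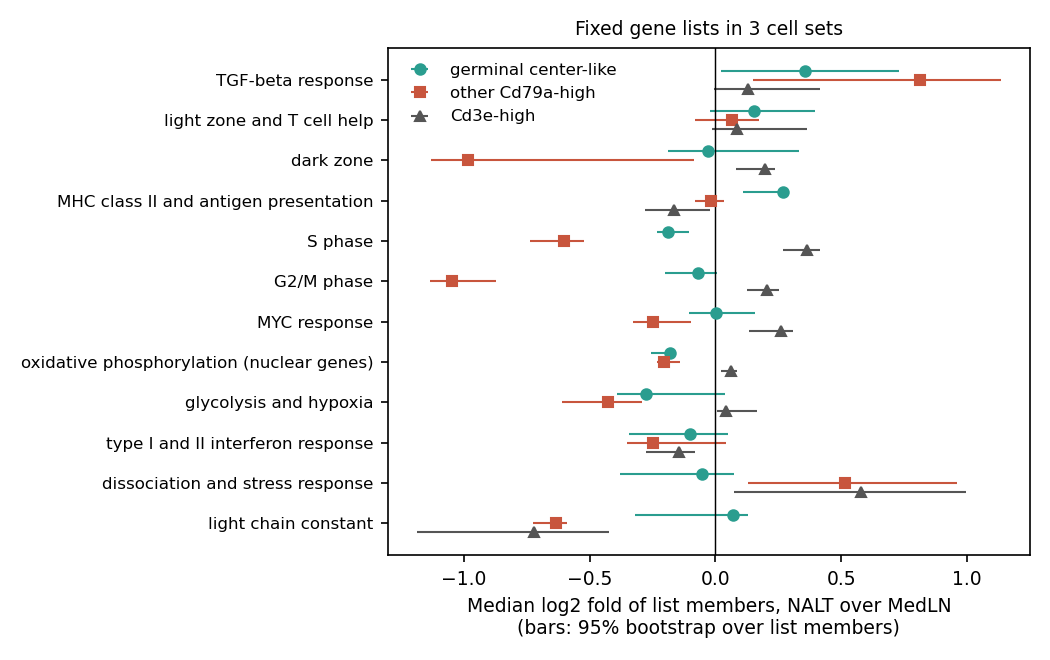
Median log2 fold of list members, NALT over MedLN (horizontal axis), for 12 fixed gene lists in 3 cell sets, with 95% bootstrap intervals over list members as bars. TGF-beta response genes stand at 0.36 in germinal center-like, 0.81 in other Cd79a-high and 0.13 in Cd3e-high cells.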

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

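The tests of doublets and of free T cell RNA were chosen only after the Cd3e-high cells had been seen, and the tests of Igha were moved to germinal center-like cells only after results had been seen. The other tests were set before their results.

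Cells with T cell transcripts made up 56.7% of NALT and 51.5% of MedLN cells in libraries labelled as sorted B cells, a signal outside the main measurement. Of Cd3e-high cells 4.90% (4.39 to 5.45) held at least 2 UMIs of Cd79a, Cd79b and Ms4a1 together. This share was kept low by the grouping, which put clusters with Cd79a in most cells in the other set. The clusters were made before that grouping, and none held both Cd3e and Cd79a in most cells. Cd79a was seen in at most 16.1% of cells of any Cd3e-high cluster. Cd3e was seen in at most 9.9% of cells of any Cd79a-high cluster. Doublets are thus argued against for most Cd3e-high cells, and a smaller part stays open. Trac stood at 112 times (103 to 121) the level of Cd79a-high cells, a ratio that picking clusters by Cd3e and Cd79a also raises. Free T cell RNA in droplets of B cells is argued against by the cluster shares instead. Cd79a was seen in at least 96.5% of cells of each Cd79a-high cluster, far above its share in Cd3e-high clusters. The co-transferred OT-II T cells may be the source of the Cd3e-high cells. Of Trbv UMIs 44.5% (42.0 to 47.1) came from Trbv12-1 and Trbv12-2, the V genes of the OT-II receptor. This share lies between the bounds set for and against and leaves that source open. Why such cells passed a GFP sort was not tested.

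The other Cd79a-high cells of NALT and MedLN fell into different clusters. A batch difference of like size in every cell type is argued against for the genes called here. They moved in Cd3e-high cells by 12.8% (9.03 to 15.5) of their size here. These genes were picked in this set, and stress genes stood higher in NALT in both sets (medians 0.51 here and 0.58 in Cd3e-high cells). With 1 library per site, a smaller shared batch part, or one of B cells alone, cannot be told from tissue. Free RNA is argued against for the genes called here as a set, at a median of 4.74% (2.73 to 6.16) of the difference in CPM. That median does not speak for Hbb-bs, which was also higher in other NALT cell sets without its top barcodes. Depth is argued against because after thinning 90.0% (88.8 to 91.1) of these cells still lay in clusters with over 80% of cells from 1 library. A difference between the tissues, including which cells the sort took there, remains an untested hypothesis that could account for it.

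Igha-led cells differed by 58.6 percentage points between NALT and MedLN in the other Cd79a-high set and by 18.8 in germinal center-like cells (44.5 after clustering again under the stricter filter), but by -35.8 in plasmablast-like cells, with 47 called cells in NALT. The opposite direction drew attention, and the difference between the sets was not tested. For germinal center-like cells free Igha RNA is argued against, since Cd3e-high NALT cells had an Igha UMI at 8.15% (6.47 to 10.2) of the germinal center-like share. Depth could contribute and stays open, as 84.6% of the difference remained after thinning but the interval (39.9 to 127) crosses both bounds set. Germline Igha transcripts from cells that still make Ighm could contribute and stay open too. An Ighm UMI was found in 13.3% of the 226 germinal center-like NALT cells with at least 3 Igha UMIs. The share was 25.7% among the 179 cells with no Igha UMI. The first is 51.7% (31.5 to 83.6) of the second. Most of these Igha-holding cells thus showed no Ighm UMI, and both shares were low. Germline transcripts from cells that make another heavy chain were not tested. A difference between the tissues stays open as well and was not tested.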

How the results depend on the processing

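Alternatives chosen only after the data were seen were the use of only Cd79a-high clusters, leaving out cells with CD3 or T cell receptor UMIs, leaving out cycling cluster 10 (genes, lists and cell cycle shares), leaving out interferon-led cluster 15 (lists), median-of-ratios scaling within cell sets, and isotype shares in the other clusterings and filters. No paired analysis was possible because the results come from no test (1 library per group). Of the values that answer a comparison, 123 stayed within their interval or 1.5-fold, 12 moved and 1 reversed; of single genes and lists 687 stayed, 116 moved and 3 reversed. The cause was not tested for those that moved or reversed, apart from the leaving out of cluster 10.

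The stricter filter asked for at least 1000 genes, at least 2000 UMIs and under 5% mitochondrial UMIs. For it, and with called doublets kept, cells were clustered again and the sets named anew. Values of cell sets there therefore mix a change of cells with a change of clusters. Under the stricter filter, passed by 2449 NALT and 2269 MedLN cells, Lyz2 library-wide reversed to a log2 fold of 0.041, and 9 of 16 named germinal center-like genes stayed at least 1.5-fold apart. The germinal center-like share difference reversed to -5.22 points and the plasmablast-like one became -7.50, and Igha-led differences became 44.5 in germinal center-like and 65.7 in other Cd79a-high cells. Without thinning, Mki67 differences were -12.4 points in germinal center-like, -11.8 in other Cd79a-high and -4.56 in Cd3e-high cells, and Top2a ones -18.6 in germinal center-like and -3.63 in Cd3e-high cells. Without cluster 10, whose cells nearly all cycle, the other Cd79a-high differences became -0.77 points for Mki67 and -0.19 for Top2a. With list members of at least 500 UMIs, the myeloid median library-wide reversed to 0.40 and the heavy chain constant median in germinal center-like cells to 0.85, and 4 in place of 7 lists were higher there; fewer members enter.

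Across the alternatives run, the Igha-led difference ranged from 13.9 to 44.5 points in germinal center-like, 57.3 to 65.7 in other Cd79a-high and -36.1 to -33.8 in plasmablast-like cells. The Cd3e-high share difference ranged from 5.21 to 6.60. The Mki67 and Top2a shares that moved without thinning depend on depth being made equal. Plasmablast-like values rest on 49 NALT cells.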

Other observations

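Both tests of list members by isotype were set before their results; the pattern they address was noticed first.

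Cd3e-high cells held Ighm at a higher share of heavy chain UMIs than B cells did. Ighm made up 83.6% of heavy chain UMIs in NALT and 76.2% in MedLN Cd3e-high cells, against 15.3% in NALT Cd79a-high cells and 57297 of 191050 such UMIs in MedLN ones. After thinning, an Ighm UMI was found in 32.1% and 33.5% of Cd3e-high cells and in 14.6% and 39.9% of germinal center-like cells. Lambda genes led 68 of 72 called NALT and 611 of 623 called MedLN Cd3e-high cells.

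Interferon genes led cluster 15 of the Cd3e-high set, with 8 NALT and 44 MedLN cells. In plasmablast-like cells Sdc1, the plasma cell marker CD138, was detected in 20.4% of NALT and 54.1% of MedLN cells, and Prdm1 in 57.1% and 68.0%, at median depths of 8701 and 18520 UMIs, unthinned.

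A hypothesis was that the higher TGF-beta response genes of NALT in the other Cd79a-high set belong to the Igha-led cells. In NALT 930 Igha-led cells were set against 414 otherwise led cells, where the list's median log2 fold was -0.10 with 6 of 15 members above 0, which is -12.4% (-108 to 28.8) of the difference between libraries. Runx3 and Id2 were at 0.78 and 1.17, and Id3 at -1.44. Among Ighm-led cells alone, 189 in NALT and 657 in MedLN, the median was 0.52 with 14 of 15 members above 0, or 63.6% (30.3 to 132) of the value in all cells. The first interval lies below the bound set for the hypothesis but reaches past the one set against it. The second crosses both of its bounds, so a part played by isotype make-up stays open. An Ighm-led call does not settle the isotype of a cell, as it can rest on 3 UMIs of 3' reads. It was met by 470 of 3237 NALT Cd3e-high cells, against 189 of 1439 NALT cells here. The Cd3e-high calls give no background rate for B cells, because thinned an Ighm UMI was in 32.1% of those cells and 19.8% here. Whether the list differs between the tissues within 1 isotype therefore stays open.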
